A study of Homo sapiens with 48 samples.

How the data were processed

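Guide DNA of HEK293A reporter cells was measured in 48 libraries, 4 for each of the high GFP, low GFP and unsorted populations of 4 conditions, and groups were taken from the sample titles. Per the labels' protocols, genomic DNA of fixed cells was amplified in a pair of PCR steps from a purchased knockout library, and all DNA of sorted cells was used. The submitters' processing notes name bcl2fastq 2.20. The tools for mapping reads to guides, for counting and for testing are not given in the sources used here, nor is a genome build, so no coordinates are printed. Gene symbols are those of the files. Of 763 symbols, 745 matched a RefSeq table of GRCh38.p14, 17 matched an older name in it and 1 had no match.

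For each condition, the authors deposited comparison tables of both sorted populations with a reference called Base, which was read as the unsorted population, the remaining group of the condition. The deposited log2 fold change of a guide, per the file headers, is the sorted population over Base. Beside it stand the deposited p-value of each guide, for each direction and for both, its false discovery rate, and a t statistic with its degrees of freedom, a score that lay on 3 to 6 degrees of freedom. The deposited gene tables hold 1 log2 fold change and p-value per gene. The deposited false discovery rates were taken as given and were not recomputed. When checked, gene log2 fold changes equalled the mean of the guides, and gene p-values equalled Fisher's combination of the guide p-values (within 0.01 on the log10 scale). One value differed: in the untreated high GFP table, the p for enrichment of the non-targeting controls stands at 0.342 in the authors' deposited table and 0.00342 by Fisher's combination, and it was not used. The sign of the t statistic and of the log2 fold change differed in 109 to 204 guides per comparison in the authors' deposited table. The authors also deposited, per library, the count of mapped and total reads, the percent of reads mapped and the mean coverage per guide. Depth was 732265 to 3279652 mapped reads per library. PCR reads were counted without molecular identifiers, as far as the labels say, so counting errors given are lower limits.

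The design fixed before the data were examined (groups, comparisons, rank aggregation, thresholds, gene lists, the rule for named genes and the other settings to try) assumed raw counts of each guide in each library. The guide tables held comparisons, 1 value per guide and comparison, so the planned count tests were not run, and the test used was rank aggregation of the authors' guide values. The guide's one-sided p-values were turned into a signed z. High against low GFP was taken as the z of high GFP minus the z of low GFP, and its size as the difference of the 2 log2 fold changes, in which Base cancels. In z it does not cancel exactly, so the ranks carry some of the error of Base. For each gene with at least 3 guides, percentile ranks of the guides among all 3152 were combined by robust rank aggregation with ranks up to 0.25, each direction against its exact null for uniform ranks, which tests the guides of a gene against the other guides and not libraries against each other. The p was 2 times the smaller, adjusted by the Benjamini-Hochberg method over 763 genes, and a gene was called at an adjusted p under 0.05. The effect of a gene is the median of its 4 guides, with the lowest and highest guide as its range, since an SE over libraries could not be had from comparison tables.

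Gene lists (15, fixed in advance) were tested in high against low GFP by the mean gene z against 100000 random gene lists of the same size, 2-sided, and the 60 tests were adjusted together. PIK3R2, HASPIN, CDK8 and STK38 of the lists were not among the genes measured under those symbols. Named genes followed a rule set in advance: in high against low, up to 10 called genes per direction by smallest p with most of the guides moving that way, or the 3 with the smallest p where fewer than 3 were called; against unsorted, up to 5 called genes per direction; and in each condition the preset genes ULK1, PIK3C3, PIK3R4, TBK1, MTOR, STK11, PRKAA1, EIF2AK3, EIF2AK4 and ERN1. List members could be named where called or largest. PIKFYVE under starvation and CDC42BPG and PDPK1 where they were not called, ULK2, ULK3, LATS1, CAMKK1 and PRKAB1 were named after their values were seen. The values of 1 gene called with clofibrate are not reported here.

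The settings chosen in advance that the tables allowed were the mean guide z against 1000000 random sets of 4 guides, the authors' deposited gene table at a false discovery rate under 0.05, and the mean log2 value for gene lists. Ranks of guides by log2 fold change, ranks among the 100 non-targeting guides, and leaving out each called gene's most extreme guide were added after the data were seen. Rank aggregation in high against low GFP and in high GFP against unsorted was tested on simulated tables. Their spread was that of the real non-targeting guides in high GFP against unsorted, and all 4 guides of a planted gene carried the same difference. The other tests were not simulated. Unchanged libraries gave 0 calls among 763 genes in each of the 4 conditions by rank aggregation, and beside planted genes at most 2 of 703 unchanged genes were called. Noise was drawn independently with the same SD for every guide of a condition, so ranks in unchanged libraries were uniform by construction. Those counts check the test and do not show how many false calls the real tables hold. With 20 genes planted at each of 3 sizes in high against low GFP, recovery was as given in the results. In high GFP against unsorted, a difference of 0.3 was recovered for 40, 20, 65 and 20 percent of genes (untreated, starvation, clofibrate, tunicamycin). A difference of 0.5 there was recovered for 95, 65, 100 and 75 percent. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.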

Results

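HEK293A, a line of human embryonic kidney cells, carried a reporter in which a single transcript encodes DsRed and a GFP fusion of p62. p62 is an autophagy receptor that is itself degraded by autophagy. The cells held a pooled CRISPR knockout library directed at kinases and related genes. They were left untreated, starved of amino acids, exposed to clofibrate at 1 mM for 6 h (peroxisomal stress) or exposed to tunicamycin at 10 µg/mL for 6 h (ER stress). Fixed cells were sorted by flow cytometry into high GFP and low GFP populations, and unsorted cells of each condition served as the reference. Guide DNA was sequenced from 4 replicate libraries of each of the 3 populations in each of the 4 conditions, 48 libraries in 12 groups. Going by the series title and design text, the comparisons ask which knockouts shift cells toward high or low GFP-p62 under each condition. A positive value means that guides against a gene were more abundant in high GFP cells.

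The tables held 3152 guides, of which 3052 targeted 763 genes with 4 guides each and 100 were non-targeting. Between 732265 and 3279652 reads per library were mapped to guides (median 2011922), which was 52.1 to 64.5 percent of the reads and 232 to 1040 mapped reads per guide. The library with the fewest mapped reads was in the untreated high GFP group, whose mean was 1841247 ± 782750 (SD, n = 4). Mapped reads averaged 2536552 ± 522609 (SD, n = 4) in the starved high GFP group and 1655217 ± 451432 (SD, n = 4) in the clofibrate unsorted group. The SD of the 100 non-targeting guides in the high against low log2 value was 0.16 untreated, 0.19 under starvation, 0.11 under clofibrate and 0.23 under tunicamycin. Counting error at this depth would give 0.04 if all guides of a library were evenly covered, which was assumed and not measured. Targeting guides had an SD of 0.19, 0.23, 0.19 and 0.18 in the same conditions, so the order of the conditions differed. In z the SD of the non-targeting guides was 1.39, 1.42, 1.02 and 0.97, lowest under tunicamycin. Nothing in the labels says that replicates came from separate cultures, so the guide values rest only on the spread between these samples. The p-values of rank aggregation are exact for the ranks of the 4 guides of a gene among all guides, and those of gene lists come from permutation over genes. Neither is a test between libraries.

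**Figure D1:**
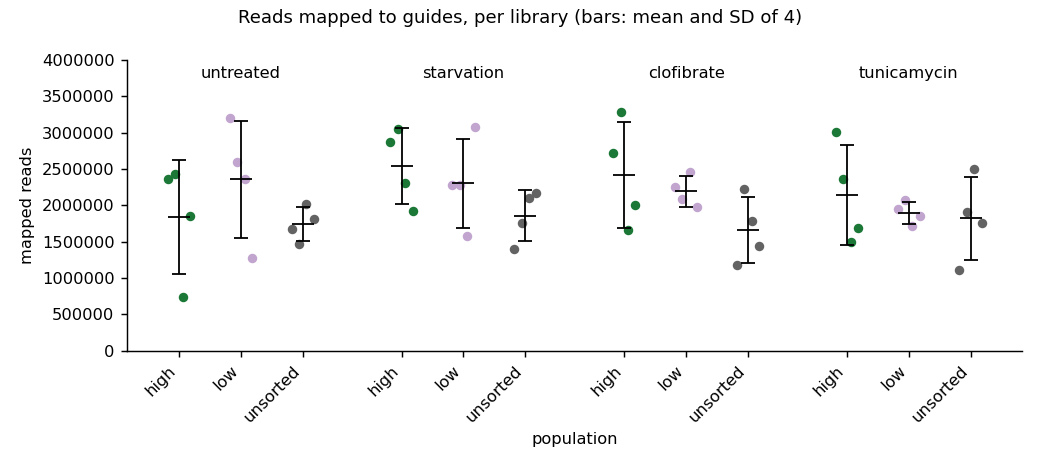
Number of reads mapped to guides in each of the 48 libraries (points), by condition and population, with the mean and SD of the 4 libraries of a group (bars). Values run from 732265 to 3279652, with the lowest point in the untreated high GFP group.

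In untreated cells, guides against PIK3C3 were 3.02-fold more abundant in high GFP than in low GFP cells. PIK3C3 is the class III phosphoinositide 3-kinase that makes phosphatidylinositol 3-phosphate on autophagosomes and endosomes, and its median log2 value was 1.59 (guides 0.95 to 1.77, exact adjusted p = 3.79e-05). PIK3R4, its regulatory subunit VPS15, rose by a median of 0.88 (guides 0.36 to 1.43, exact adjusted p = 0.000198). ULK1, the kinase that initiates autophagy, rose by 0.50 (guides 0.33 to 0.67, exact adjusted p = 0.0161). PIKFYVE, which phosphorylates phosphatidylinositol 3-phosphate further, had a median of 0.77 with 3 of its 4 guides above 0 (lowest -0.01, highest 1.66, exact adjusted p = 0.0342). In the other direction, MAP4K2, a germinal centre kinase, had a median of -0.50 (guides -0.53 to 0.14, exact adjusted p = 0.0323). TKFC, which phosphorylates dihydroxyacetone, had a median of -0.44 (guides -0.49 to -0.15, exact adjusted p = 0.0342). CDC42BPG, a kinase that binds CDC42, stood at -0.37 (guides -0.63 to -0.27) and MARK2, a microtubule affinity-regulating kinase, at -0.30 (guides -0.57 to -0.22), both with an exact adjusted p of 0.0447.

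Robust rank aggregation of the 4 guides of each gene, adjusted over 763 genes, called 4 genes higher and 4 lower in untreated high against low GFP cells. An unadjusted p under 0.05 was found for 49 genes. Of the 10 preset genes, 3 passed over all genes and 3 passed adjusted over the list alone, in both cases PIK3C3, PIK3R4 and ULK1. Medians of the preset genes that did not pass were -0.27 for MTOR, -0.17 for STK11, -0.15 for EIF2AK3, 0.10 for TBK1, 0.10 for PRKAA1 and 0.04 for EIF2AK4. ERN1 had a median of 0.00 with guides from -1.48 to 0.07. With guides ranked among the non-targeting guides, 3 genes were higher and 34 lower, and PIKFYVE was no longer called (exact adjusted p = 0.0873). PIKFYVE and CDC42BPG (both 0.0782 by mean guide z) and MARK2 (0.0536 by log2 ranks) each missed the threshold under another statistic.

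Against unsorted untreated cells, PIK3C3 (median log2 1.26, guides 0.81 to 1.39, exact adjusted p = 0.000231) and PIK3R4 (0.67, guides 0.23 to 1.01, exact adjusted p = 0.00727) rose in the high GFP population. ULK1 rose by 0.34 (guides 0.32 to 0.44, exact adjusted p = 0.0126). In low GFP cells the medians were -0.32 for PIK3C3, -0.21 for PIK3R4 and -0.13 for ULK1, and none passed over all genes. PIK3R4 there had an exact p = 0.00229 adjusted over the list alone. Rank aggregation called 3 genes higher and 0 lower in high GFP cells (47 genes at an unadjusted p under 0.05) and 0 genes in low GFP cells (41 at an unadjusted p under 0.05). In high GFP cells ULK1 missed the threshold by mean guide z (0.0722 after adjustment), and both ULK1 and PIK3R4 did among non-targeting guides (exact adjusted p = 0.0606 for each). In low GFP cells 6 genes passed by mean guide z, 2 by log2 ranks, 8 by ranks among non-targeting guides, and 9 in the authors' deposited table. For high GFP cells the authors' deposited table passed 20 genes, 12 of them with a positive log2 fold change, and gave PIK3C3 as 1.18 with a false discovery rate of 2.78e-07.

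Under amino-acid starvation, PIK3C3 guides were 3.31-fold more abundant in high GFP than in low GFP cells (median log2 1.73, guides 1.45 to 1.76, exact adjusted p = 0.000243). PIK3R4 rose by 1.03 (guides 0.91 to 1.17, exact adjusted p = 2.82e-05) and ULK1 by 0.72 (guides 0.60 to 1.04, exact adjusted p = 0.000445). PDPK1, the kinase that activates AKT, had a median of -0.67 (guides -0.92 to -0.38, exact adjusted p = 0.0276). RPS6KL1 (median -0.40, guides -0.55 to -0.21) and MAP4K2 (median -0.22, guides -0.44 to -0.02) were also lower, both with an exact adjusted p of 0.0276. TKFC had a median of -0.31 (guides -0.60 to -0.01, exact adjusted p = 0.0326). PIKFYVE had a median of 0.94 with guides from 0.06 to 1.28 and did not pass (exact adjusted p = 0.478).

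Rank aggregation called 3 genes higher and 4 lower in starved high against low GFP cells, with 47 genes at an unadjusted p under 0.05. PIK3C3, PIK3R4 and ULK1 were the 3 preset genes that passed over all genes and the 3 adjusted over the list alone. The other preset genes had medians of -0.31 for MTOR, -0.15 for STK11, -0.02 for EIF2AK3, -0.02 for PRKAA1, 0.00 for ERN1, 0.10 for EIF2AK4 and 0.11 for TBK1. With guides ranked by log2 fold change, MAP4K2 (exact adjusted p = 0.726), RPS6KL1 (0.152) and TKFC (0.393) were not called. TKFC was also not called among the non-targeting guides (0.158), where 3 genes were higher and 7 lower, and mean guide z gave 3 higher and 8 lower.

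In starved high GFP cells against unsorted cells, PIK3R4 rose by a median log2 value of 0.88 (guides 0.76 to 1.02, exact adjusted p = 0.000649) and ULK1 by 0.60 (guides 0.49 to 0.84, exact adjusted p = 0.00146). PIK3C3 had a median of 1.18 (guides 0.95 to 1.43), with an exact p = 0.0506 over all genes and 0.000663 adjusted over the list alone. In the authors' deposited table PIK3C3 stood at 1.19 with a false discovery rate of 7.78e-08. In low GFP cells PIK3C3 had a median of -0.47, with an exact p = 0.298 over all genes and 0.0234 adjusted over the list alone. Rank aggregation called 2 genes higher and 0 lower in high GFP cells (45 at an unadjusted p under 0.05) and 0 genes in low GFP cells (47 at an unadjusted p under 0.05). For low GFP cells mean guide z called 2 genes, log2 ranks 2, and ranks among non-targeting guides 3. The authors' deposited table passed 38 genes in high GFP cells and 43 in low GFP cells.

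With clofibrate, PIK3C3 guides were 2.36-fold more abundant in high GFP than in low GFP cells (median log2 1.24, guides 0.74 to 1.44, exact adjusted p = 0.00898). PIK3R4 rose by 0.78 (guides 0.49 to 1.05, exact adjusted p = 0.00614) and PIKFYVE by 0.65 (guides 0.12 to 0.91, exact adjusted p = 0.0109). ULK1 rose by 0.39 (guides 0.12 to 0.59, exact adjusted p = 0.0306) and CSNK2A2, a catalytic subunit of casein kinase 2, by 0.28 (guides 0.13 to 0.40, exact adjusted p = 0.0390). PDPK1 (median -0.78, guides -1.36 to -0.57) and STK11, the LKB1 kinase upstream of AMPK (-0.41, guides -0.49 to -0.25), fell, both with an exact adjusted p of 0.0272. MTOR, the growth kinase that represses autophagy, had a median of -0.44 (guides -1.36 to -0.15, exact adjusted p = 0.0306). HUS1, part of the DNA damage checkpoint clamp, stood at -0.60 (guides -0.78 to -0.49) and BRD3, a bromodomain protein, at -0.22 (guides -0.31 to 0.07), both with an exact adjusted p of 0.0390.

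Rank aggregation called 5 genes higher and 6 lower in clofibrate high against low GFP cells, with 63 genes at an unadjusted p under 0.05. Of the preset genes 5 passed over all genes and 5 adjusted over the list alone. The others had medians of 0.07 for TBK1, 0.09 for EIF2AK3, 0.08 for ERN1, -0.03 for PRKAA1 and -0.09 for EIF2AK4. With guides ranked among the non-targeting guides, 4 genes were higher and 20 lower, and CSNK2A2 and BRD3 were not called (exact adjusted p = 0.0625 for each). With log2 ranks BRD3 (0.463), MTOR (0.0852) and CSNK2A2 (0.0798) missed the threshold, and BRD3 also did with mean guide z (0.0760).

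Against unsorted clofibrate-treated cells, PIK3C3 rose in high GFP cells by a median log2 value of 1.03 (guides 0.78 to 1.12, exact adjusted p = 0.0114) and PIKFYVE by 0.48 (guides 0.15 to 0.63, exact adjusted p = 0.0347). CDC42BPG rose in low GFP cells by 0.47 (guides 0.38 to 0.57, exact adjusted p = 0.00335). PIK3R4 (0.69, exact adjusted p = 0.113) and ULK1 (0.37, 0.111) did not pass over all genes in high GFP cells, and both had an exact p = 0.00198 adjusted over the list alone. In low GFP cells MTOR (median 0.20), STK11 (0.16) and PIK3C3 (-0.16) did not pass over all genes. Adjusted over the list alone their exact p-values were 0.00721, 0.0315 and 0.0315. Rank aggregation called 2 genes higher and 0 lower in high GFP cells (46 at an unadjusted p under 0.05), and 1 higher and 0 lower in low GFP cells (50 at an unadjusted p under 0.05). With mean guide z PIKFYVE missed the threshold in high GFP cells (0.0710 after adjustment). The authors' deposited table passed 22 genes in high GFP cells and 2 in low GFP cells, and gave CDC42BPG as 0.47 in low GFP cells with a false discovery rate of 0.00119.

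With tunicamycin, PIK3C3 guides were 2.55-fold more abundant in high GFP than in low GFP cells (median log2 1.35, guides 0.87 to 1.62, exact adjusted p = 9.70e-05). PIK3R4 rose by 0.73 (guides 0.47 to 1.04, exact adjusted p = 0.000105). PIKFYVE (0.77, guides 0.02 to 1.37) and ULK1 (0.47, guides 0.29 to 0.66) rose, and CDC42BPG (-0.31, guides -0.46 to -0.24) and TKFC (-0.31, guides -0.38 to 0.09) fell, each with an exact adjusted p of 0.00694. EIF2AK3, which encodes the ER stress kinase PERK, had a median of 0.32 with all 4 guides above 0 (0.26 to 0.47). Its exact p was 0.162 over all genes and 0.00532 adjusted over the list alone. PKD1, the gene of polycystin-1, had a median of -0.20 and did not pass (guides -0.28 to -0.07, exact adjusted p = 0.0518).

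Rank aggregation called 4 genes higher and 2 lower in tunicamycin high against low GFP cells, with 45 genes at an unadjusted p under 0.05. Of the preset genes 3 passed over all genes and 4 adjusted over the list alone. Those not yet named had medians of -0.18 for STK11, -0.17 for EIF2AK4, -0.15 for MTOR, -0.07 for PRKAA1, 0.09 for TBK1 and 0.09 for ERN1. With guides ranked among the non-targeting guides, 5 genes were higher and 8 lower, and EIF2AK3 (exact adjusted p = 0.0463) and PKD1 (0.0196) passed. Log2 ranks gave 5 higher and 6 lower, with EIF2AK3 at 0.00538, TKFC at 0.358 and PKD1 at 0.728. By mean guide z neither EIF2AK3 (0.364 after adjustment) nor PKD1 (0.254) passed.

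Against unsorted tunicamycin-treated cells, PIK3C3 rose in high GFP cells by a median log2 value of 1.17 (guides 0.75 to 1.28, exact adjusted p = 0.000266) and PIK3R4 by 0.62 (guides 0.37 to 0.73, exact adjusted p = 0.000825). ULK1 had a median of 0.29, with an exact p = 0.0761 over all genes and 0.000998 adjusted over the list alone. EIF2AK3 had a median of 0.31 (guides 0.16 to 0.48), with an exact p = 0.231 over all genes and 0.00755 adjusted over the list alone. Rank aggregation called 2 genes higher and 0 lower in high GFP cells (46 at an unadjusted p under 0.05). In low GFP cells it called 0 genes (43 at an unadjusted p under 0.05), mean guide z and log2 ranks each also called 0, and ranks among non-targeting guides called 1. The authors' deposited table passed 13 genes in high GFP cells and 6 in low GFP cells.

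In high against low GFP, PIK3C3 and PIK3R4 stayed within the p range of the calls without their most extreme guide in all 4 conditions. This held for 2 of the 8 genes called in untreated cells, 3 of 7 under starvation (ULK1 being the other), 2 of 11 with clofibrate and 2 of 6 with tunicamycin. Against unsorted cells it held for PIK3C3 in untreated high GFP cells and for no other call. The limit was the largest p among the calls of the same comparison, so the weakest call had to match its own p. This left CDC42BPG, the 1 call in low GFP cells with clofibrate, almost no room to pass. A call that missed the limit is not thereby shown to rest on 1 guide.

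**Figure D2:**
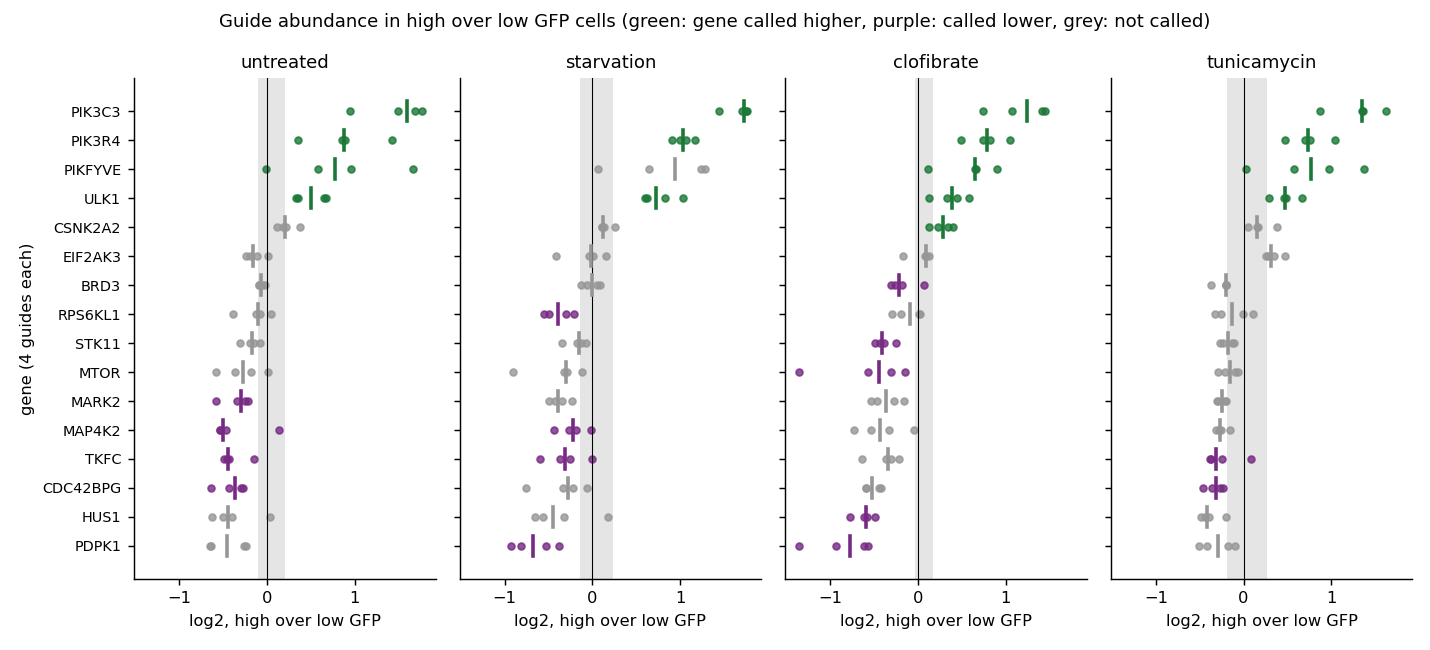
Log2 abundance in high over low GFP cells of each of the 4 guides (points) of genes called in at least 1 condition and of EIF2AK3, with the gene median (short line), in the 4 conditions. The grey band is the median ± SD of the 100 non-targeting guides, and PIK3C3 guides lie between 0.74 and 1.77 in all 4 conditions.

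**Figure D3:**
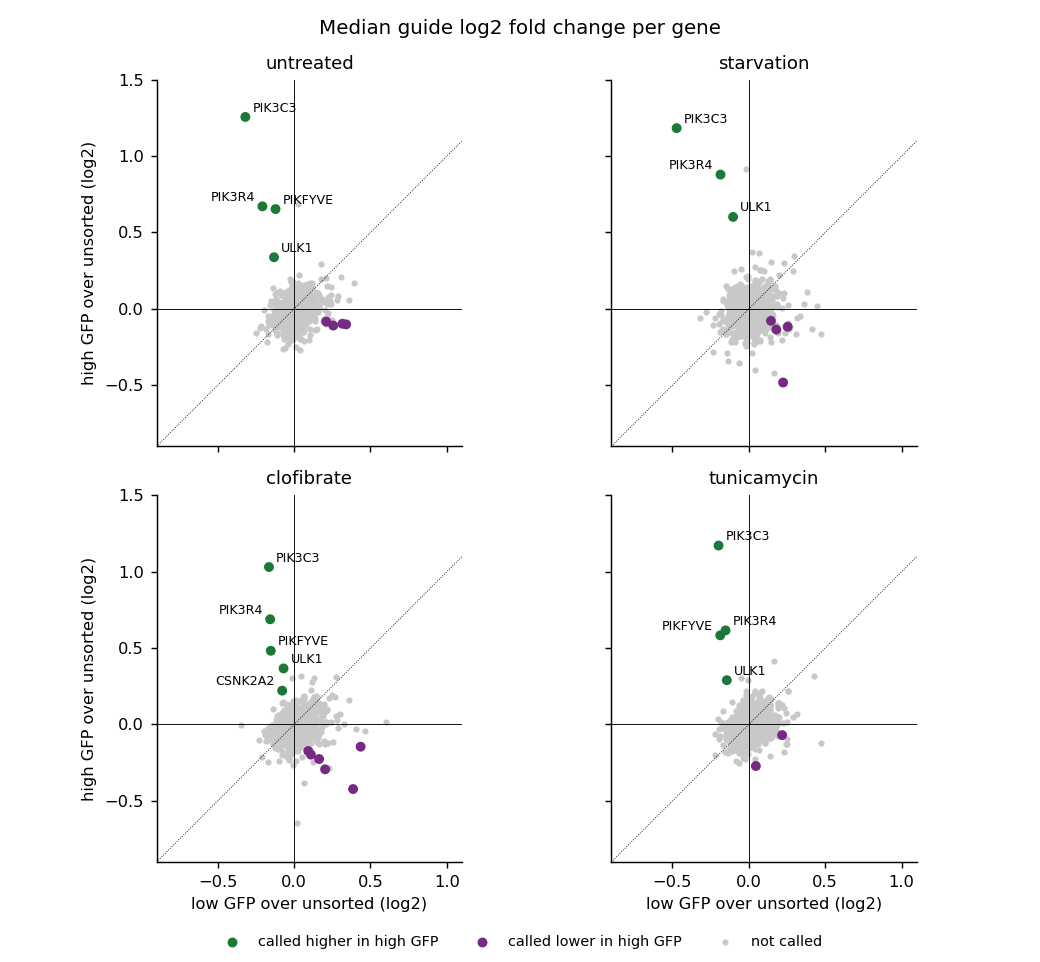
Median guide log2 fold change of each of the 763 genes in low GFP cells (horizontal axis) and in high GFP cells (vertical axis), both over unsorted cells, with points coloured by the high against low call and the dotted line marking equal values. PIK3C3 is the uppermost point in each condition, at 1.26 untreated, 1.18 under starvation, 1.03 with clofibrate and 1.17 with tunicamycin.

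Among 15 kinase lists fixed in advance, the 9 autophagy initiation kinases had a higher mean gene z than random gene lists in all 4 conditions, with 3 members called higher. In untreated, starved and tunicamycin-treated cells PIK3C3, PIK3R4 and ULK1 rose and 6 members did not pass. With clofibrate the same 3 members rose, 1 fell (STK11) and 5 did not pass. Adjusted over the list alone, 3 members were higher in each condition and 1 lower with clofibrate. The median log2 value of the 9 members was 0.10 untreated, 0.05 under starvation, 0.07 with clofibrate and 0.08 with tunicamycin. The mean gene z of the list was 1.81 untreated, 1.48 under starvation, 1.27 with clofibrate and 1.57 with tunicamycin. The adjusted p-values were 0.0006, 0.0026, 0.0141 and 0.0021 against random gene lists (permutation test, 2-sided, 60 tests adjusted together). The ULK1 relatives ULK2 and ULK3 did not pass, with medians of 0.03 and 0.10 untreated and 0.08 and -0.05 with tunicamycin.

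The 10 genes of the AMPK pathway list, which senses low cellular energy, had a mean z of -1.07 in starved cells (permutation test, adjusted p = 0.0397), and an adjusted p of 0.198 by mean log2 value. None of its 10 members passed over all genes in starved cells. Adjusted over the list alone 2 were lower, CAMKK1 (median -0.30, exact p = 0.0423) and PRKAB1 (-0.17, exact p = 0.0460). STK11 was the 1 member called in another condition, lower with clofibrate, where the list had a mean z of -0.46 (permutation test, adjusted p = 0.608).

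Of the 16 PI3K-AKT-mTOR growth signalling genes measured, MTOR and PDPK1 fell with clofibrate and PDPK1 fell under starvation. The list did not pass in any condition (permutation test, smallest adjusted p = 0.301). PIKFYVE gave the 3 member calls among the 14 phosphoinositide kinases outside classes I and III (permutation test of the list, smallest adjusted p = 0.359). MAP4K2 gave the 2 member calls among 13 Hippo pathway kinases (permutation test of the list, smallest adjusted p = 0.190). In that list LATS1 had a median of 0.22 under starvation, with an exact p = 0.00861 adjusted over the list alone. MARK2 was the 1 call among 13 AMPK-related kinases (permutation test of the list, smallest adjusted p = 0.359). CSNK2A2 was the 1 call in each of the lists that hold it, the 9 casein kinases and the 9 mitophagy and organelle quality kinases (permutation test, smallest adjusted p = 0.143 and 0.129). No member of the 6 eIF2-alpha and unfolded protein response kinases passed over all genes. With tunicamycin that list had a mean z of 0.69 (permutation test, adjusted p = 0.359), and EIF2AK3 had an exact p = 0.0128 adjusted over the list alone.

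No member passed over all genes among the 24 mitosis and DNA replication kinases, the 22 JNK and p38 cascade kinases, the 19 PKA and PKC genes, the 18 transcription and splicing kinases and the 10 ERK cascade kinases. Their smallest adjusted p-values as lists were 0.172, 0.661, 0.503, 0.301 and 0.638. The 17 blood-lineage kinases, fixed as a background list for a kidney line, also had no member call, with mean z between 0.09 and 0.21 (permutation test, smallest adjusted p = 0.661). In all, 5 of the 60 list tests passed, and 11 had an unadjusted p under 0.05. Lists were chosen from general knowledge of these pathways and hold the preset genes, so the autophagy list and the preset genes are not separate evidence.

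**Figure D4:**
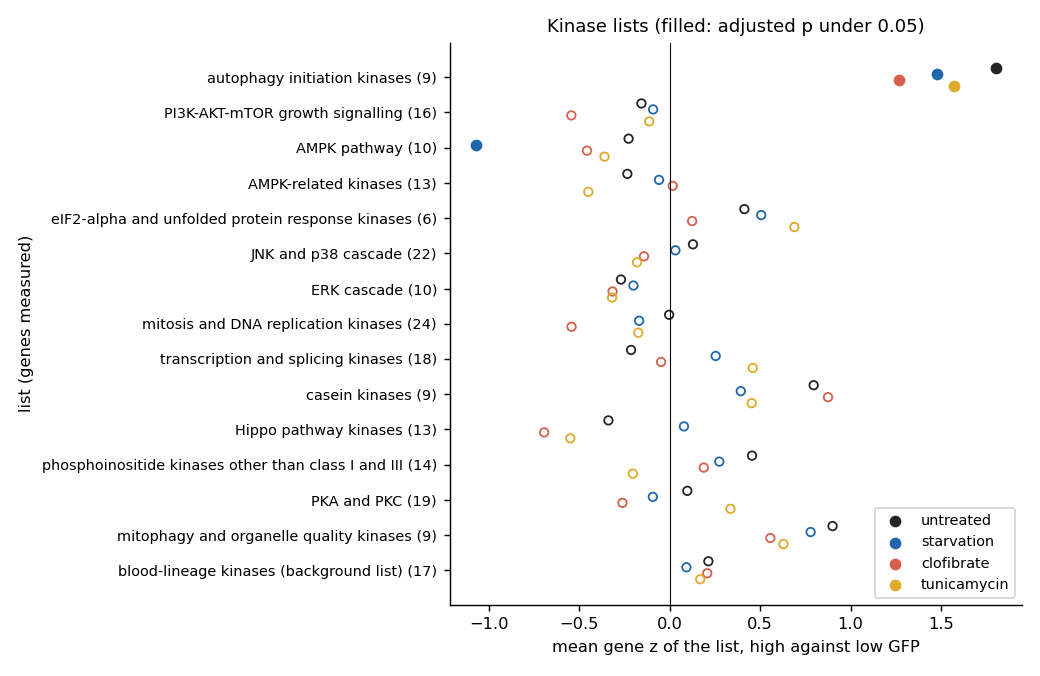
Mean gene z in high against low GFP cells (horizontal axis) of each of the 15 kinase lists in the 4 conditions, with filled points for lists past an adjusted p of 0.05. The autophagy initiation kinases are the rightmost points in all 4 conditions, between 1.27 and 1.81.

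Each condition was tested on its own, so a gene that passed in 1 condition and not in another is not thereby shown to differ between them. The medians of PIKFYVE, CSNK2A2, MARK2, PDPK1 and CDC42BPG had the same sign in all 4 conditions. CDC42BPG had medians of -0.28 under starvation (exact adjusted p = 0.447) and -0.52 with clofibrate (exact adjusted p = 0.0691). PDPK1 had medians of -0.45 untreated (exact adjusted p = 0.407) and -0.30 with tunicamycin (exact adjusted p = 0.933). In simulated tables, a difference of 0.3 was recovered for 45 percent of genes untreated, 15 percent under starvation, 60 percent with clofibrate and 25 percent with tunicamycin. A difference of 0.6 was recovered for 100, 95, 100 and 100 percent, so effects near 0.3 were often not detectable at this spread. All 4 guides of a planted gene carried the full difference. The spread was that of non-targeting guides in high GFP against unsorted (SD 0.14, 0.18, 0.12 and 0.18). Genes with uneven guides were not simulated, and PIKFYVE, with a median of 0.94 under starvation, was not called. Larger effects can therefore be missed too.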

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

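The tests of differences between conditions, and the weighing of EIF2AK3, were chosen after the results were seen. The design fixed in advance allowed tests of such differences only on raw counts. Those given here used the deposited comparisons and so depart from it.

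In the untreated high GFP group, 61.2 percent of the reads of replicate 2 were mapped to guides, apart from the other libraries at 56.7 to 57.4 percent. In the tunicamycin low GFP group, 62.3 percent of the reads of replicate 3 were mapped, with the others at 57.0 to 57.6 percent. These 2 libraries came from 24 tests of a group and a measure for a single outlying library, and chance gives such a result in about 1 in 20. In the unsorted population, replicate 1 had the lowest percent of reads mapped in all 4 conditions (54.3 untreated, 54.2 under starvation, 54.4 with clofibrate and 52.1 with tunicamycin), which was not tested.

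High against low GFP values were compared between each stress and untreated cells by rank aggregation of guide differences. With guide z, 0 of 763 genes passed in each of the 3 stresses, with 35, 37 and 36 genes at an unadjusted p under 0.05 for starvation, clofibrate and tunicamycin. With guides ranked by log2 fold change, 2, 0 and 1 genes passed. For starvation these were CLP1, an RNA kinase of tRNA splicing, with a median difference of -0.47 (guides -1.50 to -0.38, exact adjusted p = 0.0248, 0.961 by z). The other was CSNK2B, the regulatory subunit of casein kinase 2, with -0.57 (guides -0.80 to -0.36, exact adjusted p = 0.0291, 0.961 by z). Adjusted over the list of preset genes alone, none passed by guide z, and by log2 ranks 2 passed with clofibrate and EIF2AK3 with tunicamycin (exact adjusted p = 0.000113). With clofibrate PIK3C3 lay below untreated cells by a median of -0.30 (guides -0.42 to -0.22, exact adjusted p = 0.0186, 0.526 by z). ERN1, the ER stress kinase IRE1, had a median difference of 0.06 (guides -0.03 to 1.63, exact adjusted p = 0.0465, 0.526 by z). That median ranked 193 from the top among 763 genes, so a shift of its guides as a set is not shown.

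EIF2AK3, the PERK kinase of ER stress, was the gene past the threshold for tunicamycin, with guides further toward high GFP than in untreated cells by a median of 0.45 (4 of 4 guides, 0.40 to 0.59, exact adjusted p = 0.00863 by log2 ranks). As the whole difference, untreated libraries out of line would leave tunicamycin level with the other stresses. But tunicamycin lay above the mean of starvation and clofibrate by 0.321 (4 of 4 guides, 0.16 to 0.64). A median this large was reached by 5 genes, EIF2AK3 among them, though the comparison reuses the tunicamycin values for which the gene was picked. As part of the difference, untreated libraries out of line cannot be told apart from a smaller change in each stress. The reason is that clofibrate lay above untreated cells by 0.162 (4 of 4 guides, 0.07 to 0.27) while starvation was at 0.07 (-0.18 to 0.27). Chance among the genes screened stays open, since by guide z the adjusted p was 0.970 over all genes and 0.125 adjusted over the list alone. Tunicamycin libraries out of line, and a biological effect of ER stress, stay open and were not tested.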

How the results depend on the processing

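Ranks by log2 fold change, ranks among non-targeting guides and leaving out a guide were chosen after the data were seen, while mean guide z, the authors' deposited table and the mean log2 value for lists were planned. No paired analysis was possible because the guide tables give 1 value per comparison and not per library. For the same reason median-of-ratios and total-count normalization, the fit without a low-count filter, the other guide test, the replicate block, leaving out each replicate, the planned interaction fits and other splits of the samples were not run.

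No gene called in high against low GFP changed direction with mean guide z, log2 ranks or ranks among non-targeting guides. In high against low GFP, where 8, 7, 11 and 6 genes were called (untreated, starvation, clofibrate, tunicamycin), ranks among non-targeting guides gave 37 untreated, 24 with clofibrate and 13 with tunicamycin, of which 7, 8 and 6 were shared with the genes called. Mean guide z gave 11 under starvation and log2 ranks 11 with tunicamycin (7 and 5 shared). In high GFP against unsorted, where 3, 2, 2 and 2 genes were called, log2 ranks gave 7 untreated, 7 under starvation and 7 with clofibrate, ranks among non-targeting guides 1 untreated and 4 with clofibrate, mean guide z 5 with tunicamycin, and 20, 38, 22 and 13 passed in the authors' deposited table. In low GFP against unsorted, where 0, 0, 1 and 0 were called, mean guide z gave 6, 2 and 2 in the first 3 conditions, log2 ranks 2, 2 and 5, ranks among non-targeting guides 8, 3, 9 and 1, and 9, 43, 2 and 6 passed in the authors' deposited table. Explanations for the authors' deposited table and for ranks among non-targeting guides are weighed in the other observations, and for the other settings the cause was not tested. The other counts stayed within 1.5 times, and 4 of the 5 list tests past the threshold (2 lists) also passed by mean log2 value (1 list).

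Of the 32 calls in high against low GFP, 29 were kept with mean guide z, 27 among non-targeting guides and 23 with log2 ranks. Of the 10 calls against unsorted cells, mean guide z did not keep ULK1 untreated and PIKFYVE with clofibrate, and ranks among non-targeting guides did not keep PIK3R4 and ULK1 untreated. With tunicamycin, EIF2AK3 gained a call among non-targeting guides and with log2 ranks, and PKD1 among non-targeting guides. In 5 cases without a call the sign differed. Without a gene's most extreme guide, 2 of 8, 3 of 7, 2 of 11 and 2 of 6 genes stayed within the p range of the calls, and PIK3C3 and PIK3R4 did so in all 4 conditions. Against unsorted cells 1 of 3 untreated calls (PIK3C3) did so in high GFP cells, 0 of 2 in each of the other conditions, and 0 of 1 in low GFP cells with clofibrate. A test on fewer guides gives larger p-values by construction, and the limit was the largest p among the calls of the same comparison. A call that missed it is therefore not shown to rest on 1 guide. In simulated tables a difference of 0.3 in high against low GFP was recovered for 15 to 60 percent of genes, so smaller effects are not excluded at this spread.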

Other observations

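Tests on the mean of the 4 conditions, correlations between conditions and the test of random non-targeting sets were chosen after the results were seen, while the tests of guide direction and of the blood-lineage guides were written down before their results.

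Averaged over the 4 conditions, rank aggregation of the high against low GFP guide values called 5 genes higher and 11 lower, and log2 ranks called 22, of which 15 were shared. All 16 genes called by z had the same sign in each condition, which follows in part from choosing them by this mean. Among them 3 were called in no single condition. LRPPRC, which stabilises mitochondrial mRNAs, had a median of -0.40 (guides -0.55 to -0.29, exact adjusted p = 0.00135), RPS6KA4, the stress kinase MSK2, -0.42 (guides -0.60 to 0.06, exact adjusted p = 0.00565) and WNK1, a kinase of ion transport, -0.22 (guides -0.38 to -0.11, exact adjusted p = 0.0137, 0.121 by log2 ranks). PDPK1 averaged -0.59 (exact adjusted p = 2.06e-05) and CSNK2A2 0.19 (exact adjusted p = 0.000275). The 4 values come from 1 library of guides, so the conditions are not separate screens.

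For the mean of both sorted populations against unsorted cells over the 4 conditions, guides were ranked by log2 fold change. Ranks by z were not run for it. ACTR2, a subunit of the actin-nucleating Arp2/3 complex, had a median of -0.23 (exact adjusted p = 0.000387 by log2 ranks), with -0.37 in high GFP and -0.08 in low GFP cells. Passing this test does not show a change in both populations, which were not tested apart. PIK3C3 (0.43), PIK3R4 (0.29) and PIKFYVE (0.27) passed in the opposite direction to ACTR2, and PIK3C3 had medians of 1.18 in high GFP and -0.31 in low GFP cells. CLP1 (0.23, exact adjusted p = 0.0250), the cell cycle kinase CDK1 (0.20, exact adjusted p = 0.0283) and the SRC-inhibiting kinase CSK (0.18, exact adjusted p = 0.0335) also lay above unsorted cells. Across the 3052 targeting guides, which are not independent replicates, high against low values of 2 conditions correlated with r from 0.281 to 0.352 and rho from 0.133 to 0.218 over 6 pairs, and without PIK3C3, PIK3R4, ULK1 and PIKFYVE r was 0.159 to 0.264. For the 100 non-targeting guides r was -0.406 to 0.010 and rho -0.133 to 0.0430, and the pair with r of -0.406 (untreated and tunicamycin) had a rho of 0.0430.

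Over the 8 comparisons with unsorted cells, the authors' deposited table had 153 passes by 119 different genes, and 143 of these passes were not called by rank aggregation of the same guides. Guide p-values that are too small even for non-targeting guides may be part of this. In 8 of 8 comparisons more than 5 percent of random sets of 4 non-targeting guides reached a combined 2-sided p under 0.05 (7.20 to 34.9 percent). These guides were also shifted as a set, with a median z of -0.53 in untreated and -0.58 in starved low GFP cells (targeting guides -0.02 in each). In starved high GFP cells, at 24.2 percent of sets, their median z was -0.14. A shared shift can give small combined p-values, so the sets cannot tell it from guide p-values that are too small. The sets redraw the same 100 guides, of which 10.75 percent (SE over guides 1.11) had a p under 0.05 on average, and the 95 percent exact binomial interval lay above 5 percent in 3 comparisons and included it in 5. The non-targeting guides as 1 set had a false discovery rate in that table of 0.00165 in high GFP and 4.87e-07 in low GFP cells under starvation, where 38 and 43 genes passed, and of 0.0751 to 0.544 in the other 6 comparisons. The 2-sided combination ignores the direction of the guides. In 69.2 percent of those passes (99 of 143) the gene had guides on both sides of 0, against 83.9 percent of all genes over the same comparisons. Such genes were thus no more common among these passes than among all genes, so the share cannot decide whether ignored direction is a cause. No biological explanation was tested.

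Targeting guides lay below non-targeting guides in high against low GFP by -0.0572 log2 on average over the 4 conditions (permutation p = 0.0003), and in starved cells alone by -0.03 (permutation p = 0.156). DNA breaks at any target may be part of this, since guides against 17 blood-lineage kinases also lay below the non-targeting guides, by -0.0511 (SE 0.0117, permutation p = 4e-05), though in single conditions this was -0.02 under starvation (permutation p = 0.495) and -0.06 with tunicamycin (permutation p = 0.0518). Loss of kinases that the cells express cannot be told apart from no such effect, as blood-lineage guides differed from the other targeting guides by 0.00618 (SE 0.00981, permutation p = 0.708). Whether HEK293A cells express these kinases was not measured here. By construction, ranks among guides that lie higher move targeting guides toward the lower direction.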
